A study of Mus musculus with 64 samples.

How the data were processed

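Gene expression was measured in early distal convoluted tubules (DCT), the short nephron segment downstream of the macula densa that reabsorbs sodium chloride through the cotransporter NCC. Per the labels, the tubules were dissected by hand from kidneys of Pvalb-tdTomato transgenic C57BL/6 mice, in which cells that express parvalbumin fluoresce red, and every dissection was done between 9 and 11 am. The mice ate a diet with furosemide, a loop diuretic that blocks sodium chloride uptake in the thick ascending limb just upstream of the DCT, for 12, 24, 48 or 96 h, or a control diet. Each of the 4 times had its own control mice. The 64 libraries form 16 groups of 4 by sex, diet and time. The labels number the replicates and do not say that each is a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

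Total RNA was extracted with a column kit, cDNA was made with the SMART-Seq HT kit and libraries with the Nextera XT kit, per the labels' protocols. This chemistry amplifies full-length cDNA from small inputs and carries neither strand information nor molecular identifiers. The deposited values are estimated counts per gene (expected counts that need not be whole), which the authors made with Salmon, per the submitters' processing notes, which also name the build GRCm38.p6. The annotation release, the read trimming and the way transcript estimates were summed to genes are not given in the sources used here. Salmon shares reads among near-identical sequences by a model, so genes with close paralogs or pseudogenes are uncertain, as are overlapping and antisense genes in data without strand. Of the values, 55% were whole numbers, and all were rounded to whole counts before use. The table holds 54331 genes, of which 560 were at 0 in all libraries. By gene identifier, 54097 were matched to a symbol and position in GENCODE release M21 of GRCm38, and 234 were not. No column of the table was left unused.

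Total counts ranged from 12.71 to 41.07 M (1e+06 counts) per library, with a median of 20.45 M. Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the rounded counts, with trimmed mean of M-values (TMM) scaling. The filter filterByExpr with its minimum count of 10 left 41507 genes. The 64 libraries were fitted together with 1 mean per group, so that the groups shared the estimate of spread, and each comparison was a contrast of group means: furosemide against control in each sex at each time, the mean of both sexes at each time, the difference between the sexes, the difference between the times, and sex and time within the controls. Values of p were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with the default prior count of edgeR's fit, and each standard error (SE) was derived from the fold change and its F statistic. A prior count of 2 was used for the log2 CPM values of the list tests and marker scores. Expression levels per library are counts per 1e+06 counts (CPM) with TMM scaling unless CPM of all counts is stated.

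The 33 gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, again with the correlation between genes estimated from the data, and with fry. Camera compares a list with all other genes, and fry tests whether the genes of a list move, on balance, one way. These list p-values were adjusted over the 33 lists within a comparison. The gene lists, the tests, the rule for named genes and a set of alternatives were fixed before the data were examined. For each comparison of diets in both sexes, the rule named genes with an adjusted p under 0.05, an average of at least 3 log2 CPM, and the same sign with an unadjusted p under 0.05 in each sex, taking the 8 largest changes in each direction. For sex it named the 8 largest differences in each direction with an adjusted p under 0.05 and the same minimum level. Predicted and clone-based gene models were skipped. It added the 2 to 4 members of each list with the smallest p, and always Slc12a3, Pvalb, Trpm6 and Egf. A few genes that the rule or the lists pick are not reported here. Genes outside this rule are marked in the text as chosen after their values were seen.

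The procedure was tested on simulated counts drawn from the means and library sizes of the real libraries for furosemide against control in both sexes at 96 h, with 200 of 41507 genes changed. It recovered 39 of 100 genes changed by 1 on the log2 scale and 99 of 100 changed by 2, with 15 false calls, and made 0 calls in the unchanged 48 h comparison. The simulated counts were independent between genes and had 1 average level per gene apart from the changed genes. They lack the structure of the real libraries described below, so they do not show how often the procedure errs on those. No pair of libraries within a group agreed within counting noise, since the smallest chi-square per degree of freedom over 96 pairs was 14.63. Libraries of the same replicate number deviated together in 1 of the 8 comparisons of diets within a sex and time, females at 24 h, where the 4 pairs correlated by 0.18 to 0.581. There the blocked count is given beside the result. Xist, Ddx3y and Eif2s3y levels matched the labelled sex in the 64 libraries.

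The alternatives fixed before the data were examined were DESeq2 (1.42.0), limma's voom with sample quality weights, DESeq2's size factors in place of TMM, no filter on low counts, the replicate number as a block, scores of thick ascending limb and proximal tubule markers as covariates, only the libraries of a comparison in its fit, and each library left out in turn. Others were chosen after seeing the data. These were to leave out the 3 libraries whose median Spearman correlation with their group mates lay under 0.75, to leave out those and 1 further 48 h library, to test only genes with an average of at least 3 log2 CPM, to use the level of Lars2 as a covariate, to leave out the 5 furosemide libraries at 96 h with more Lars2 than any control of that time, and, for sex and time in controls, to leave out the 96 h libraries. Lars2 encodes the mitochondrial leucyl-tRNA synthetase, took between 3727 and 46140 CPM of all counts, and was used there as a mark of library structure. The closing section gives the effects of these alternatives.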

Results

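Transcripts of early distal convoluted tubules were compared between mice fed furosemide and mice fed a control diet, in males and females, after 12, 24, 48 and 96 h, with 4 libraries in each of the 16 groups. The design asks how this segment responds over time when a loop diuretic acts upstream of it. Total counts per library ranged from 12.71 to 41.07 M. The libraries of the 96 h groups were deeper (median 32.4 M, n = 16) than those of 12 to 48 h (median 19.15 M, n = 48), held less Lars2 (median 10600 against 36130 CPM of all counts) and had a lower share of mitochondrial counts (median 10.78% against 17.83%).

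Every library was rich in the transcript of NCC, Slc12a3, with a median of 6380 CPM of all counts and a range of 4060 to 12180. Markers of other segments were lower: the medians were 115.6 CPM for Slc12a1, the furosemide-sensitive cotransporter of the thick ascending limb, 8.674 CPM for Slc34a1, a phosphate transporter of the proximal tubule, and 1.668 CPM for Aqp2, the water channel of collecting duct principal cells. Umod, a thick ascending limb product, had a median of 4446 CPM, far above that of Slc12a1. In male control 24 h replicate 2 it reached 9393 CPM, above the 5881 CPM of Slc12a3 there. Which cells the Umod transcripts came from was not tested. Of the 64 libraries, 3 correlated poorly with the other libraries of their group. The median Spearman correlations were 0.448 for female control 24 h replicate 3, 0.702 for female control 48 h replicate 4 and 0.721 for male furosemide 12 h replicate 4, and the next lowest was 0.811.

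**Figure D1:**
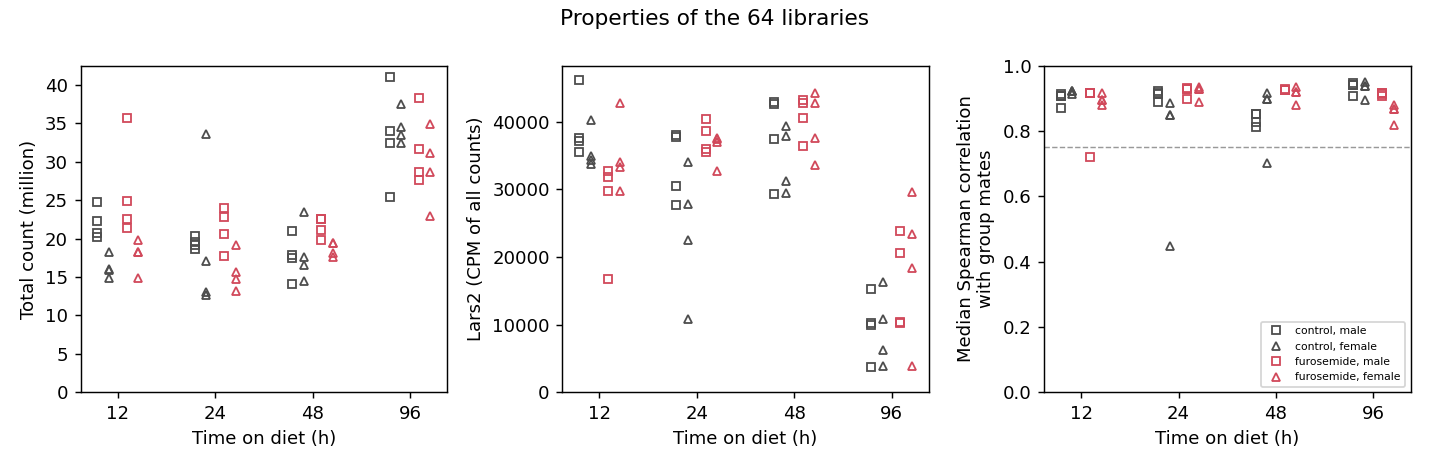
Total count in M (1e+06 counts), Lars2 level in CPM of all counts and median Spearman correlation with group mates of the 64 libraries, against time on diet in h; squares are males, triangles females, grey control and red furosemide, and the dashed line marks a correlation of 0.75. The 96 h libraries are deeper and lower in Lars2, and 3 libraries lie under the dashed line.

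After 12 h of furosemide, the transcripts of cholesterol synthesis enzymes stood higher in tubules of both sexes. All 20 measured members had a positive log2 fold change, with a median of 0.68 (0.58 in males and 0.82 in females, n = 8 per diet over both sexes). Examples are Sqle, squalene epoxidase (0.98, SE 0.243), Fdps, farnesyl diphosphate synthase (1.02, SE 0.31), and Lss, lanosterol synthase (0.76, SE 0.217). Sqle averaged 91.3 ± 45.2 CPM with furosemide against 46 ± 11.5 CPM in controls (SD, n = 8). All 17 glycolytic genes were likewise positive, with a median of 0.67, led by Ldha, a lactate dehydrogenase subunit (1.22, SE 0.332), and Pfkp, a phosphofructokinase (0.92, SE 0.252).

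Camera called the cholesterol list (adjusted p = 5.73e-18) and the glycolysis list (adjusted p = 3.15e-11), and both calls were lost when the correlation between genes was estimated, with adjusted p = 0.159 and adjusted p = 0.313. In all, 11 of 33 lists were called at 12 h, 0 with an estimated correlation and 0 by fry. Among them were oxidative phosphorylation, positive for 26 of 26 genes (median 0.39, adjusted p = 0.538 with an estimated correlation), heat shock (median 0.41, adjusted p = 0.538 with an estimated correlation) and ribosome biogenesis (median 0.33, adjusted p = 0.514 with an estimated correlation). Podocyte markers were the 1 list called lower (median −1.51, adjusted p = 0.538 with an estimated correlation). Adjusted over the list alone, 16 cholesterol and 11 glycolysis genes passed. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in both sexes together, with 3663 at an unadjusted p under 0.05, while DESeq2 called 96 and voom 2. Without female furosemide 12 h replicate 3 the count was 2.

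After 24 h, Pdk4 (ENSMUSG00000019577), a kinase that shuts down pyruvate dehydrogenase, fell by 1.90 on the log2 scale (SE 0.376), from 65 ± 52.7 to 17.2 ± 3.01 CPM, and lay below the control median in 8 of 8. Also called were Gadd45b, a stress-induced regulator of growth arrest (−2.04, SE 0.383), and the predicted gene Gm4459 (−9.21, SE 1.72), both outside the naming rule and chosen after their values were seen. Of the 20 cholesterol genes 18 were positive, with a median of 0.44 and 7 passing adjusted over the list alone. Insig1, a sterol sensor (1.07, SE 0.334), and Sqle (0.70, SE 0.242) were among those 7.

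The adjusted p was 0.0425 for Pdk4 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which called 4 genes in all, 1 higher and 3 lower. Pdk4 lost its call in 13 of the 16 fits that left out 1 library (adjusted p up to 0.217), and the count moved to 0 without male furosemide 24 h replicate 1, 3 or 4 or female furosemide 24 h replicate 2, 3 or 4, to 1 or 2 without 6 others, to 8 without female control 24 h replicate 1 and to 11 without replicate 4 of that group. Camera called the cholesterol list (adjusted p = 4.49e-12, adjusted p = 0.634 with an estimated correlation) and 3 others: heat shock (median 0.27), proximal tubule markers (median 0.38) and erythroid markers (median 2.80), each with adjusted p = 0.996 with an estimated correlation. The oxidative phosphorylation list was not called, and its median and mean were −0.29 and −0.27 while camera's direction was up. Its median was 0.34 in males and −0.96 in females, whose controls include the library with the lowest similarity. Without the 3 libraries of low similarity the both-sex median was 0.44 and camera called the list higher (adjusted p = 0.405 with an estimated correlation), and the heat shock median was 0.66 (0.657).

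After 48 h, transcripts of energy metabolism stood higher in both sexes. All 26 genes of oxidative phosphorylation were positive with a median of 0.63 (0.56 in males, 0.70 in females). They include Ndufs1 of complex I (0.68, SE 0.207), Cox5a of complex IV (0.77, SE 0.256) and Atp5o of the ATP synthase (0.69, SE 0.208). Of 17 glycolytic genes 15 were positive with a median of 0.83, with Ldha at 1.41 (SE 0.333), from 139 ± 53.5 to 391 ± 170 CPM (SD, n = 8), and Pfkp at 1.03 (SE 0.253). Of 12 heat shock genes 11 were positive with a median of 0.64, with the mitochondrial chaperones Hspd1 at 0.88 (SE 0.202) and Hspe1 at 0.95 (SE 0.247) and the cytosolic chaperone Hspa8 at 0.95 (SE 0.25). The 1 gene called was Tubb2b, a beta-tubulin, which rose by 1.40 on the log2 scale (SE 0.26), from 24.7 ± 9.03 to 64.9 ± 11.4 CPM, and lay above the control median in 8 of 8 libraries. It is ENSMUSG00000045136, on chromosome 13 from 34126748 to 34130466 of GRCm38, and close tubulin copies leave its count uncertain.

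Adjusted over the list alone, 23 of the 26 oxidative phosphorylation genes, 12 of the 17 glycolytic and 7 of the 12 heat shock genes passed, against 0 over all genes. Camera called 17 of 33 lists, 16 of them higher. The adjusted p was 2.4e-24 for oxidative phosphorylation, 6.58e-16 for glycolysis and 3.62e-11 for heat shock, and these calls were lost with an estimated correlation (adjusted p = 0.138, adjusted p = 0.0922 and adjusted p = 0.0989), as were the other 14. Fry called 4 lists, these 3 and the S phase list (adjusted p = 0.0334, 0.0265, 0.0267 and 0.0267). Immune markers were also positive in 12 of 12 genes (median 0.56, adjusted p = 0.359 with an estimated correlation), and erythroid markers were lower (median −5.24, adjusted p = 0.392 with an estimated correlation).

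By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Tubb2b had an adjusted p of 0.0497 and lost its call in 10 of 16 fits that left out 1 library (up to 0.339); 3926 genes had an unadjusted p under 0.05. The 48 h count moved from 1 to 0 without 10 single libraries, to 2 without male furosemide 48 h replicate 1, to 4 and 5 without female furosemide 48 h replicates 3 and 4, and to 6 without male control 48 h replicate 2. Without the 3 libraries of low similarity the count was 1266 (1133 higher). Without these and female furosemide 48 h replicate 2 it was 473 (365 higher), of which 420 were among the 1266. Both sets were chosen after seeing the data, and the set of 4 was tried before the 3 were picked by their correlation. With the 3 libraries left out, 23 oxidative phosphorylation, 13 glycolysis and 8 heat shock genes were called higher over all genes. With the 4 left out these were 15, 9 and 5, and with a voom fit of all libraries the count was 891.

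**Figure D2:**
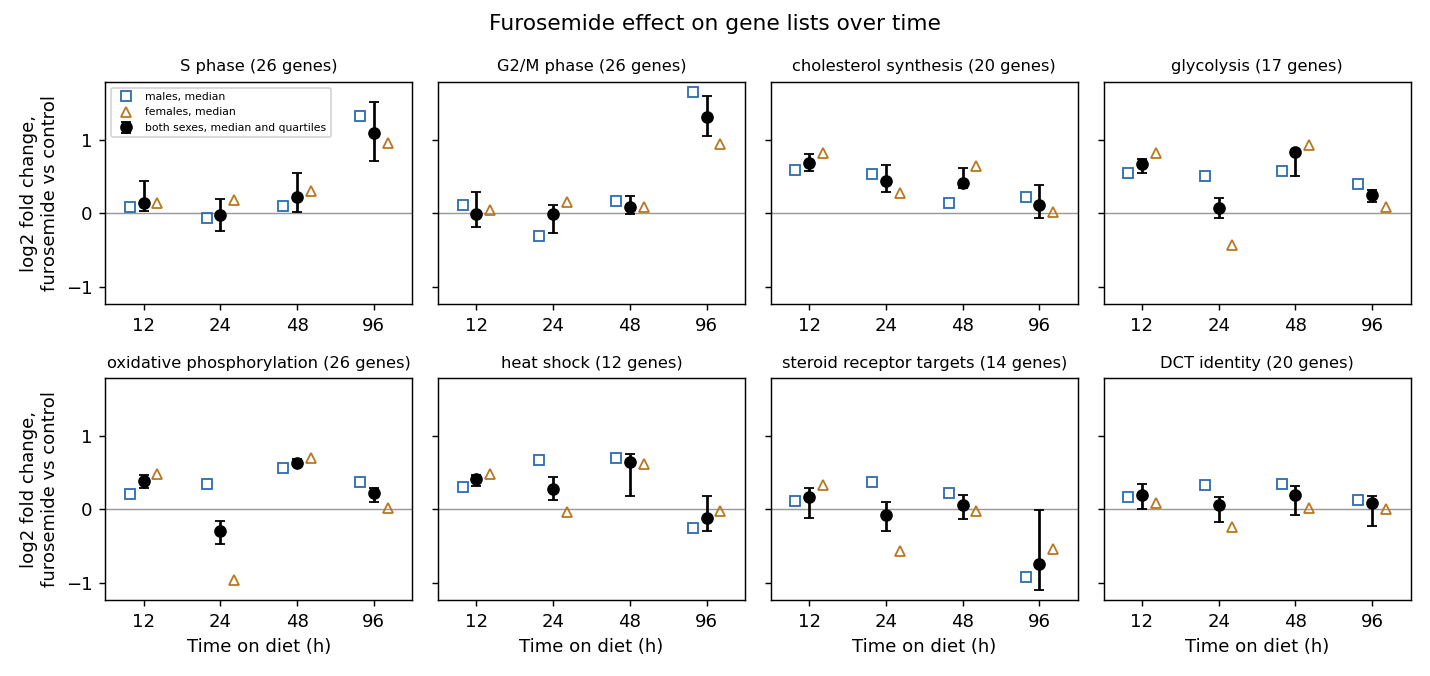
Log2 fold change, furosemide against control, of 8 gene lists against time on diet in h; black points and bars give the median and quartiles over the genes of a list in both sexes together, blue squares the male median and brown triangles the female median. The S phase and G2/M medians stand at 1.09 and 1.31 at 96 h, the cholesterol median at 0.68 at 12 h and the steroid receptor target median at −0.74 at 96 h.

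After 96 h, genes of DNA replication and mitosis rose in both sexes. Mcm5 (ENSMUSG00000005410, chromosome 8 from 75109569 to 75128439 of GRCm38), a subunit of the replicative helicase, rose by 1.70 on the log2 scale (SE 0.186), from 6.15 ± 0.697 to 20.4 ± 5.66 CPM (SD, n = 8). Its partners Mcm6 and Mcm2 rose by 1.82 (SE 0.33) and 1.26 (SE 0.2), Rrm2, the small subunit of ribonucleotide reductase, by 1.63 (SE 0.304), Cdca3, which promotes entry into mitosis, by 1.73 (SE 0.318), Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, by 1.32 (SE 0.222), and Stmn1, a microtubule destabiliser, by 1.67 (SE 0.363). Each of these 7 genes lay above the control median in 8 of 8 furosemide libraries. Bc1, a noncoding RNA gene, rose by 1.24 (SE 0.26) and lay above it in 7 of 8. In the same libraries 4 named genes fell: Pdk4 by 2.16 (SE 0.378), Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, by 1.91 (SE 0.404), and the glucocorticoid-induced genes Fkbp5 by 1.80 (SE 0.326) and Tsc22d3 by 1.64 (SE 0.325). Fkbp5 (ENSMUSG00000024222, chromosome 17 from 28399094 to 28517527) averaged 47.4 ± 15.6 CPM against 166 ± 48.4 CPM in controls, and Tsc22d3 (ENSMUSG00000031431) 48.9 ± 19.4 against 151 ± 31.6 CPM. Over the controls of all times, Fkbp5 averaged 101 CPM in females and 62 CPM in males, and Tsc22d3 89.9 and 67.1 CPM (n = 16 per sex). The 96 h controls thus lay high among controls in both genes. These 2 falls do not show levels below those of controls at other times.

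All 26 genes of the S phase list were positive, with a median of 1.09 (1.32 in males, 0.96 in females), 9 called over all genes and 20 adjusted over the list alone. All 26 genes of the G2/M list were positive, with a median of 1.31 (1.64 in males, 0.94 in females), 6 called over all genes and 23 adjusted over the list alone, among them the mitotic kinase Cdk1 (1.83, SE 0.356), its regulatory cyclin Ccna2 (1.76, SE 0.393), and Birc5, an inhibitor of apoptosis that acts in mitosis (1.16, SE 0.225). Of the 14 steroid receptor targets 10 were negative, with a median of −0.74, 2 called over all genes and 5 adjusted over the list alone. Beside Fkbp5 and Tsc22d3 those 5 were Zbtb16, a transcription factor (−1.48, SE 0.35), Usp2, a deubiquitinase (−1.01, SE 0.279), and Sgk1, a kinase that raises sodium transport (−1.11, SE 0.352), none of the 3 called over all genes. The receptor genes themselves, Nr3c1 (0.23, SE 0.234) and Nr3c2 (0.40, SE 0.251), were not called.

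EdgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 34 genes at 96 h, 29 higher and 5 lower, of which 15 belong to the S phase or G2/M list. The adjusted p was 2.63e-08 for Mcm5, 0.00071 for Mcm2, 0.00238 for Pdk4 and 0.00327 for Fkbp5. Camera called 12 of 33 lists, of which S phase (adjusted p = 3.61e-66), G2/M (4.56e-71) and steroid receptor targets (1.11e-11) held with an estimated correlation (adjusted p = 1.86e-14, 1.05e-07 and 0.0141) and by fry (2.72e-13, 2.33e-06 and 0.0337). Markers of neighbouring cells moved too by camera alone: thick ascending limb markers were higher (median 0.68), markers of connecting tubule and late DCT lower (median −0.60) and intercalated cell markers lower (median −0.87), with adjusted p = 0.146, adjusted p = 0.146 and adjusted p = 0.264 with an estimated correlation. In 5 of the 8 furosemide libraries of 96 h, Lars2 lay between 18340 and 29630 CPM of all counts, above every control of that time (up to 16360 CPM).

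The count of 34 became 18, 19 and 22 without female control 96 h replicate 2, male control 96 h replicate 3 or female control 96 h replicate 4, 80 without female control 96 h replicate 1 and 90 without female furosemide 96 h replicate 1, and 3 (1 of them among the 34) without the 5 libraries high in Lars2, a comparison chosen after seeing the data that leaves 2 male and 1 female furosemide libraries. Mcm5, Mcm6, Mcm2, Rrm2, Cdca3, Ube2c, Pdk4, Fkbp5 and Tsc22d3 kept their call in all 16 fits that left out 1 library, while Stmn1 lost it in 8 (adjusted p up to 0.142), Bc1 in 7 (up to 0.125) and Gclc in 5 (up to 0.115). With Lars2 as a covariate Fkbp5 (−1.37, SE 0.336), Tsc22d3 (−1.23, SE 0.313) and Bc1 (0.58, SE 0.187) were no longer called, with adjusted p = 0.0917, adjusted p = 0.123 and adjusted p = 0.469. Over the alternatives the adjusted p ranged from under 0.0001 to 0.894 for Fkbp5 and to 1 for Tsc22d3 and Bc1. Of the 12 named genes, Mcm5 alone was called without the 5 libraries high in Lars2. There the folds of Mcm6, Mcm2, Ube2c, Pdk4, Gclc and Fkbp5 were 2.05, 1.14 (1.135), 1.19, −1.81, −3.10 (−3.095) and −1.67 (−1.665), with larger SEs, such as 0.427 against 0.33 for Mcm6. Those of Rrm2, Cdca3, Stmn1 and Tsc22d3 were smaller, at 1.33, 1.43, 1.495 and −1.19, and Bc1 was at −0.06 (−0.058).

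**Figure D3:**
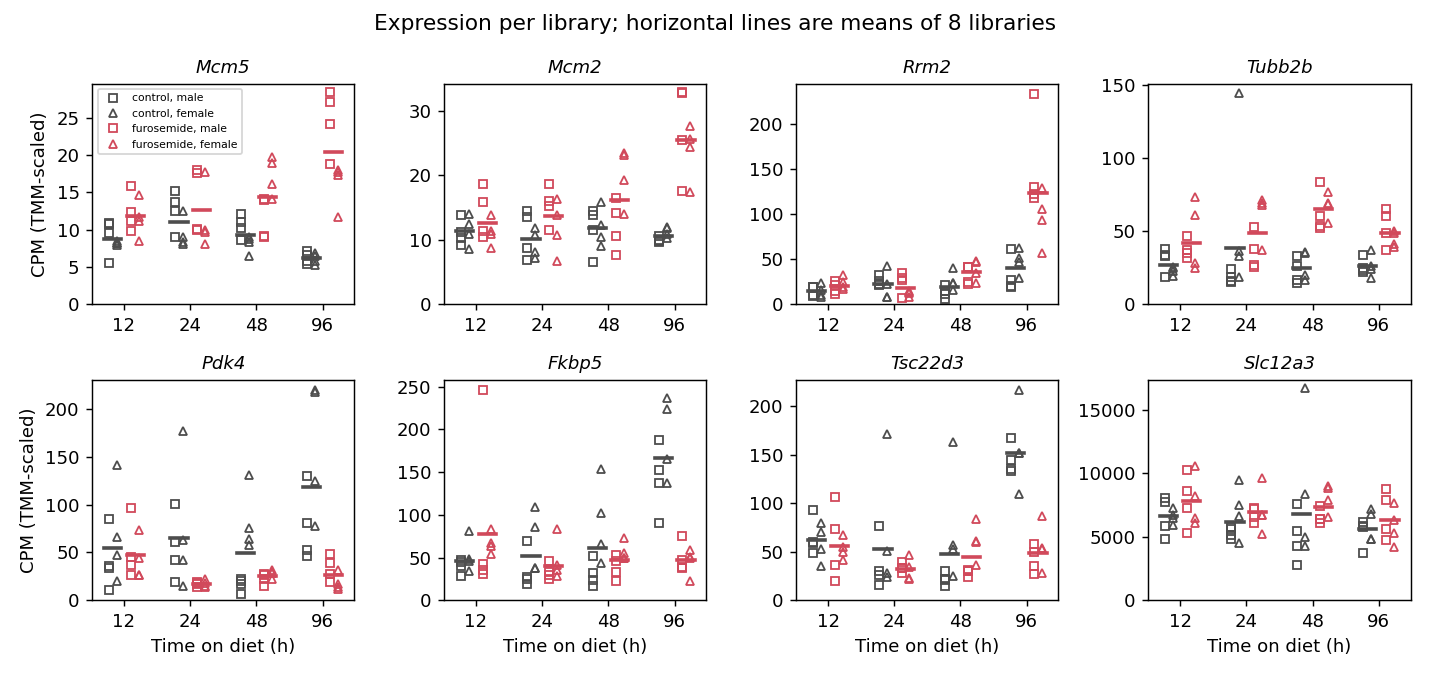
Level in CPM with TMM scaling of 8 genes in every library against time on diet in h; squares are males, triangles females, grey control and red furosemide, and bars are means of 8 libraries. At 96 h Mcm5 averages 6.15 CPM in controls and 20.4 CPM with furosemide, and Fkbp5 166 and 47.4 CPM, while Slc12a3 averages 5630 and 6310 CPM.

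With all libraries, NCC itself and the other 19 genes of the DCT identity list were not called at any time by edgeR. The log2 fold change of Slc12a3 (ENSMUSG00000031766, chromosome 8 from 94329201 to 94366214) in both sexes was 0.25 at 12 h (SE 0.227) and 0.18, 0.16 and 0.16 at 24, 48 and 96 h (SE 0.226), with means between 6310 and 7850 CPM under furosemide and between 5630 and 6790 CPM in controls (n = 8 at each time). Single libraries left out moved it between 0.08 (0.082) and 0.32 (0.319) at 24 h, without female furosemide 24 h replicate 3 or female control 24 h replicate 3. At 48 h it moved between 0.04 (0.043) and 0.43, without female control 48 h replicate 2 or 4. It was 0.49 at 48 h without the 3 libraries of low similarity. Pvalb, the calcium buffer parvalbumin that marks early DCT, had −0.21, −0.57, 0.39 and 0.13 (SE 0.277). Without female control 24 h replicate 3 the 24 h value of Pvalb was 0.08 (0.079) and that of Trpm6 0.08 (0.077). Egf, the growth factor made in this segment, had 0.005, −0.17, −0.18 and 0.17 (SE 0.247). Trpm6, the apical magnesium channel, had −0.46, −0.20, −0.18 and −0.69 (SE 0.253, and 0.254 at 96 h), lay below the control median in 8 of 8 furosemide libraries at 12 h and at 96 h, and had an adjusted p of 0.792 at 96 h by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while voom called it there. Without the 3 libraries of low similarity, Kcnj10 (1.23, SE 0.254), Wnk4, a kinase upstream of NCC (0.76, SE 0.22), and Fxyd2, a sodium pump subunit (0.74, SE 0.215), were called higher at 48 h. The list of 20 DCT identity genes had medians of 0.19, 0.05, 0.19 and 0.09, and was called by camera at 48 h alone (adjusted p = 0.000367, adjusted p = 0.396 with an estimated correlation). The list of 17 regulators of NCC had medians of 0.31, 0.07, 0.20 and −0.06, and was called at 48 h (adjusted p = 0.359 with an estimated correlation), where the basolateral potassium channel gene Kcnj10 had 0.95, and at 96 h, where it was lower (adjusted p = 0.653 with an estimated correlation). Without the 3 libraries the medians at 24 and 48 h were 0.28 (0.279) and 0.39 (0.393) for DCT identity and 0.31 (0.307) and 0.51 (0.505) for regulators of NCC.

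Within each sex, with 4 libraries per diet, few genes passed. In males at 96 h, Mcm5 (1.99, SE 0.266), Cdca3 (2.45, SE 0.461), Rrm2 (2.24, SE 0.438), Ube2c (1.77, SE 0.318) and Mcm2 (1.44, SE 0.284) rose. In females at 96 h, Mcm5 rose by 1.41, while Pdk4 fell by 3.12 and Angptl4, a lipase inhibitor induced by fasting, fell by 4.28 on the log2 scale. In males at 12 h the interferon-induced GTPase gene Iigp1 fell by 4.11 (SE 0.756, adjusted p = 0.0424 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 0 genes called without male control 12 h replicate 2 or any 1 of the 4 furosemide libraries. These genes fall outside the naming rule for 1 sex and were chosen after their values were seen. The 5 male calls at 96 h became 1 without male control replicate 3 or male furosemide replicate 1, 2 without male control replicate 2 and 3 without male furosemide replicate 3, and the 3 female calls became 0 without female control replicate 4 or female furosemide replicate 2, 3 or 4 and 9 without female control replicate 1.

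In females at 24 h, 113 genes were called, 2 higher and 111 lower, and 16 of the 113 had the same sign in males. With the replicate number as a block shared by all 64 libraries, which does not pair the diets within this group, the count was 0. This count was 0 without female control 24 h replicate 3, the library with a correlation of 0.448, or without any 1 of the 4 furosemide libraries, and it was 1413, 914 and 1200 without replicate 1, 2 or 4 of the controls. The count was 0 in females at 12 h, males at 24 h, males at 48 h and females at 48 h, with 2771, 2762, 2601 and 3042 genes at an unadjusted p under 0.05. DESeq2 called 44, 70, 61 and 80 genes there and voom 0, 0, 2 and 7. Single libraries left out moved 2 of these counts: males at 24 h had 1 without male furosemide 24 h replicate 2, and females at 48 h had 6, 6 and 7 without female furosemide 48 h replicate 1, 3 or 4.

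Whether the response differed between the sexes was tested directly. No gene was called at 12, 24, 48 or 96 h or for the mean of the times by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, so the calls made in 1 sex alone are not shown to be specific to it. At an unadjusted p under 0.05 there were 2581, 4768, 2344, 417 and 2411 genes, DESeq2 called 72, 396, 43, 17 and 34, and voom 0, 1, 0, 6 and 0. Among genes whose furosemide effect differs by sex, 12 h gave 1 without male control 12 h replicate 1. Among genes whose furosemide effect differs by sex, 24 h gave 1069, 712 and 1 without female control 24 h replicate 1, female control 24 h replicate 4 or male furosemide 24 h replicate 2. Camera called 5 lists with a more negative furosemide effect in females over the mean of the times: DCT identity (median difference −0.26), regulators of NCC (−0.25), magnesium handling (−0.31), oxidative phosphorylation (−0.33) and mitochondrial fatty acid and ketone oxidation (−0.23). With an estimated correlation each had an adjusted p of 0.832. Without the 3 libraries of low similarity none of the 5 was called by camera (adjusted p from 0.498 to 0.97), and the direction turned for regulators of NCC and oxidative phosphorylation. Egf had the largest difference of the 4 segment genes followed throughout (−0.55, SE 0.247, adjusted p = 0.842).

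Across the 11622 genes with an average of at least 3 log2 CPM, the male and female fold changes had a Pearson correlation of 0.29 at 12 h, −0.114 at 24 h, 0.328 at 48 h and 0.507 at 96 h, and a Spearman correlation of 0.339, −0.345, 0.441 and 0.5. Genes are not independent replicates, and these are correlations across genes with no shared libraries. The value at 24 h was 0.397 without female control 24 h replicate 3, and that at 12 h was 0.0456 without male furosemide 12 h replicate 4. Between times, the both-sex fold changes at 12 and 48 h had a Pearson correlation of 0.413 (Spearman 0.493) and those at 24 and 96 h 0.178 (Spearman 0.105). The other pairs of times were near 0: −0.0749 for 12 and 24 h, 0.0405 for 12 and 96 h, 0.0254 for 24 and 48 h and 0.0856 for 48 and 96 h.

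Whether the response differed between times was tested in the same way. The effect on 5 genes differed over the 4 times: Mcm5, with log2 fold changes of 0.45, 0.21, 0.61 and 1.70 at 12, 24, 48 and 96 h, Lig1, which encodes DNA ligase I (0.17, −0.52, 0.43 and 1.501), Igha, the constant region of the IgA heavy chain, and the predicted genes Gm4459 and Gm2907. Between 96 h and 12 h directly, Fkbp5 was the 1 gene called, with a difference of −2.55. Of these 6, Lig1, Gm4459 and Gm2907 lie outside the naming rule and were chosen after their values were seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Mcm5 had an adjusted p of 0.0265 and Fkbp5 of 0.0226. Male furosemide 12 h replicate 4, a library of low similarity, held 247 CPM of Fkbp5 against 30.3 to 42 in the others of its group. The 12 h side of the Fkbp5 difference therefore rests in part on 1 library. The count of 5 ranged from 0 to 6 over fits that left out 1 library, with 0 without female control 24 h replicate 3 or male furosemide 24 h replicate 2, and that of 1 from 0 to 2.

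In the controls, 515 genes differed by sex, 231 higher and 284 lower in females (n = 16 libraries per sex). Beside Xist, the inactive X transcript (3.86, SE 0.209), the genes higher in females were led by Tmem128, a membrane protein gene (2.11), Sec61g, a subunit of the protein translocation channel (1.96), Fkbp2, a folding enzyme of the endoplasmic reticulum (1.42), Phlda3, a p53 target (1.35), Angptl4 (1.34), Gcdh, a mitochondrial enzyme of lysine breakdown (1.31), and Srp54b of the signal recognition particle (1.27). Fkbp2 averaged 285 ± 151 CPM in females and 105 ± 37.3 CPM in males (SD, n = 16). Lower in females were the Y-linked Ddx3y (−4.88) and Eif2s3y (−4.22), Kap, the androgen-regulated kidney protein (−3.36, SE 0.479), the antibody chains Igkc (−3.24) and Igha (−3.24), Htra1, a secreted protease (−1.86), Iigp1 (−1.68) and Lyz2, the macrophage lysozyme (−1.41). Uty (−0.48) and Kdm5d (−0.36), which have X-linked copies, were not called and are uncertain. Uty averaged 44.7 CPM in females and 62.4 CPM in males, and the source of the female counts was not tested. Slc12a3 averaged 7020 ± 2960 CPM in females and 5590 ± 1410 CPM in males (log2 difference 0.33, SE 0.16, adjusted p = 0.413).

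Among lists, the 17 regulators of NCC were higher in females in 17 of 17 genes (median 0.32) and the 20 DCT identity genes in 18 (median 0.26), neither with any gene called. Markers of proximal tubule (median −0.62), immune cells (−0.63), podocytes (−1.21) and principal cells (−1.02) were lower in females. Camera called 18 of 33 lists, 0 with an estimated correlation, where the adjusted p was 0.458 for each of these 6. Fry called 1, the check list of sex chromosome genes (adjusted p = 0.000401). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the count of 515 stayed between 416 and 590 when any 1 library was left out. Its balance of directions varied, with 239 higher and 69 lower in females over abundant genes alone, 357 and 268 without the 96 h libraries, and 169 and 317 without the 3 libraries of low similarity. Igkc lost its call in 18 of these 32 fits (adjusted p up to 0.557), Srp54b in 17, Angptl4 in 15 and Lyz2 in 14, Htra1 in 2, Igha without male control 96 h replicate 2 (0.258) and Iigp1 without male control 12 h replicate 2 (0.178). Single libraries carried much of some differences: without male control 12 h replicate 3 Htra1 was at −0.73 (−0.731), without male control 12 h replicate 2 Iigp1 was at −0.73 (−0.734), and without male control 96 h replicate 2 Igkc was at −1.51 and Igha at −1.98 (−1.976).

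Among controls, 3492 genes differed over the 4 times. The count was 0 when the 96 h libraries, deeper and lower in Lars2 than the rest, were left out, a comparison chosen after seeing the data. It was 7230 without female control 24 h replicate 3 and 2303 without female control 96 h replicate 2. The controls of each time were compared only with furosemide libraries of the same time above.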

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

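The tests below of Lars2, of left-out libraries and of markers of other cells were chosen after the results they bear on had been seen. The comparison with random lists, the clock score and the other splits of the libraries were written down before they were run, with the patterns and counts they test already seen.

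The rise of replication and mitosis genes at 96 h drew attention because the effect on Mcm5 and Lig1 differed between times (adjusted p = 0.0265 and 0.0459 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and because the 96 h libraries differ in depth and Lars2. With Lars2 as a covariate the median log2 fold change of the 26 S phase genes was 1.16 (quartiles 0.71 and 1.69) against 1.09 without it, which argues against the structure marked by Lars2 as the whole cause. With thick ascending limb and proximal tubule marker scores as covariates it was 1.04 (quartiles 0.60 and 1.39). The higher of the upper quartiles of immune and stromal markers was −0.09 (−0.0895), far below the S phase median. These values argue against a greater amount of such cells as the whole cause. They cannot show which cells were cycling, since a few cycling cells could raise genes of low level without moving the markers. Other cell types were not tested in this way. Leaving out the 5 libraries high in Lars2 leaves 2 male and 1 female furosemide libraries. Most calls were lost there, while the S phase median was 1.04 (quartiles 0.51 and 1.41), about the same fold. The G2/M median was not taken in that fit. Among Mcm5, Mcm6, Mcm2, Rrm2, Cdca3, Ube2c and Stmn1, Mcm6 alone had a larger fold there, and Cdca3 had 1.43 against 1.73 with all libraries. Why the calls were lost for mitosis genes was not tested. No biological explanation was tested.

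Higher transcripts of oxidative phosphorylation, glycolysis and heat shock at 48 h, a list result with 1 gene called, were weighed because 1266 genes were called when 3 libraries were left out. The median over the 55 members was 0.64 with all libraries (quartiles 0.56 and 0.72), 0.76 (0.755) without the 3 libraries of low similarity and 0.70 (0.701) with the Lars2 covariate, which argues against both as the whole cause. The median with all libraries lay above 100% of 10000 random lists matched on mean expression, whose median was 0.37 and highest value 0.54. Genes of the same level thus rose too, by less. The lists were picked by their rise, and random lists do not keep the correlation between members. The rank therefore does not settle how much of the rise a shift of abundant genes accounts for. How many genes changed stays open as well, and no biological explanation was tested.

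Lower steroid receptor targets at 96 h were weighed because the effect on Fkbp5 differed between 96 h and 12 h. Its adjusted p was 0.0226 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 12 h side of that call includes male furosemide 12 h replicate 4, with 247 CPM of Fkbp5 against 30.3 to 42 in its group mates. The 96 h side is set against controls of that time, which lay high in Fkbp5 and Tsc22d3 among controls. A different hour of the clock was tested with a score of clock genes, which differed between diets at 96 h by −0.26 (−0.262, SE 0.291); its interval reaches past 0.5 in size, so a shift of the clock stays open. With the Lars2 covariate the median of the 14 targets was −0.69 (−0.687) against −0.74, but the upper quartile moved from −0.01 to 0.20, and Fkbp5 and Tsc22d3 were no longer called, with smaller folds (−1.37 and −1.23), so library structure stays open too and the pattern cannot be told apart from it. A lower glucocorticoid or mineralocorticoid signal stays open as untested, since hormone levels were not analysed here.

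The other genes whose effect differed between times were Gm4459 (adjusted p = 0.0265), Gm2907 (0.0456) and Igha (0.0456), with fold changes of opposite sign at different times, such as 6.15 at 12 h and −9.21 at 24 h for Gm4459, −7.71 and 2.47 at 12 and 48 h for Gm2907, and −4.01 and 4.65 at 12 and 24 h for Igha.

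Of 256 sets of 4 libraries tested for 1 value far from the other 3, 22 stood out where chance gives about 13. Female control 24 h replicate 3 had 2.40% (2.399%) of its counts from mitochondrial genes against 12.62% to 14.24% in the others of its group, a Spearman correlation of 0.448 (0.4477), 2540 CPM of Pvalb against 288 to 626, and 144 CPM of Tubb2b against 18.7 to 36.3. Male furosemide 12 h replicate 4 had a correlation of 0.721 (0.7214), 4010 CPM of Egf against 2000 to 2130 and 247 CPM of Fkbp5 against 30.3 to 42. Female control 48 h replicate 4 had a correlation of 0.702. The correlation also stood out, within a narrow range, for male control 12 h replicate 3 (0.870, or 0.8704), male furosemide 24 h replicate 2 (0.899, or 0.8985), female furosemide 24 h replicate 3 (0.889, or 0.8886) and, as the highest of its group, male furosemide 48 h replicate 4 (0.930, or 0.9295).

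Single genes stood out in further libraries. Slc12a3 was at 3740 CPM in male control 96 h replicate 2 against 5750 to 6140 in the others of its group. Pvalb was at 319 CPM in female furosemide 48 h replicate 2 (714 to 789) and 305 in female furosemide 96 h replicate 2 (568 to 593). Egf was at 2470 CPM and Mcm5 at 11.7 CPM in female furosemide 96 h replicate 1 (1350 to 1520 and 17.3 to 18 in the others), and Rrm2 was at 234 CPM in male furosemide 96 h replicate 1 (118 to 130). Fkbp5 was at 69.8 CPM in male control 24 h replicate 1 (19.3 to 26.7) and Tsc22d3 at 23.9 CPM in male furosemide 48 h replicate 1 (30.4 to 30.7). Female furosemide 24 h replicate 1 had 36.9 CPM of Tubb2b (68.1 to 71.4) and 32670 CPM of all counts of Lars2 (37030 to 37640).

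Other splits of the same libraries were fitted in the same way, 20 drawn at random beside the real one. The smallest share they can give is 1 of 21, and with 13 counts above 0 tested in this way about 1 could reach it by chance. For furosemide in both sexes at 96 h the real split was 1 of 21 with as many genes, with 34 against at most 3. This argues against chance for this count, but at the smallest share possible it does not exclude chance. For females at 96 h the real split was 1 of 21 too, but with 3 against at most 1. That is a small margin for a count that was 0 without female control replicate 4 or female furosemide replicate 2, 3 or 4, so chance is not excluded there. For 48 h without the 3 libraries of low similarity it was 1 of 21 as well (1266 against at most 2). That fit was chosen after seeing the data, and the splits do not cover this choice, so chance is not excluded there. For time in controls the real split was 1 of 21 by a small margin (3492 against at most 2955).

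Chance cannot be excluded for the other counts either, which further splits reached. As many genes came from 2 of 21 splits for males at 96 h (5 against at most 14), 2 for both sexes at 24 h (4 against at most 604), 4 for both sexes at 48 h (1 against at most 248), 12 for males at 12 h (1 against at most 345) and 17 for females at 24 h (113 against at most 2729). They came from 2 for the effect that differs by time (5 against at most 7), 4 for 96 h minus 12 h (1 against at most 1), 2 for sex in controls (515 against at most 4303) and 3 for 96 h without the libraries of low similarity (112 against at most 859). Where the real count was 0, all 21 splits gave as many. Splits that call several times the real count, as at 12, 24 and 48 h and for sex in controls, point to a structure of the samples other than diet or sex.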

How the results depend on the processing

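Counts below are of genes called, and their order over times is 12, 24, 48 and 96 h. A count is given where it moved by more than 1.5 times, and the cause of each move was not tested unless stated. The alternatives without libraries, with abundant genes only and with Lars2 were chosen after the results were seen. Test: DESeq2 in place of edgeR gave 96, 95, 120 and 174 in both sexes, 92, 70, 61 and 55 in males, and 44, 1122, 80 and 29 in females. For sex differences in the effect it gave 72, 396, 43 and 17, and 34 for the mean of times. It gave 24 for the effect that differs by time, 52 for 96 h minus 12 h and 5445 for time in controls. The correlation between sexes was 0.166 at 24 h, reversed, and 0.271 at 96 h. Voom gave 2, 16, 891 and 1515 in both sexes, 2 in males at 12 h, 2 at 48 h and 715 at 96 h, and 3, 7 and 460 in females at 24, 48 and 96 h. For sex differences it gave 1 at 24 h and 6 at 96 h. It gave 76 for the effect that differs by time, 71 for 96 h minus 12 h and 11883 for time in controls. Its correlations between sexes were 0.107, 0.252 (reversed), 0.534 and 0.573. All 34 genes called at 96 h were also called by DESeq2 and by voom. Scaling: DESeq2's size factors gave 350 in females and 9 in both sexes at 24 h. They moved the median log2 fold change of all genes at 48 h from −0.10 (−0.103) to −0.22 (−0.224). Filter: without a filter the count was 35 in females at 24 h, 4 in females at 48 h and 3 for the effect that differs by time. Testing abundant genes alone gave 20, 15 and 82 in both sexes at 24, 48 and 96 h, 328, 3 and 7 in females and 8 in males at 96 h. It gave 4 for 96 h minus 12 h, 308 for sex in controls and a correlation of 0.399 at 48 h. Lists: of 198 list tests 67 were called by camera, 3 with an estimated correlation and 8 by fry. With abundant genes alone these were 39 and, with an estimated correlation, 2. With an estimated correlation, 3 were called with the replicate block, 4 without the libraries of low similarity and 2 with the Lars2 covariate. Model: with the replicate number as a block shared by all 64 libraries the count was 0 in males at 12 h, 0 in females at 24 h, 0 for 96 h minus 12 h and 31 in both sexes at 96 h. Over all comparisons the numbers do not pair the diets, since 10 of 32 pairs of the same number correlated above 0.1 and 3 of 32 libraries correlated best with their own number. In females at 24 h all 4 pairs correlated above 0.1 (0.18 to 0.581), but 1 of the 4 control libraries correlated best with its own number. The block took the count there from 113 to 0. Its terms are shared by all 64 libraries, so this was not a paired test of the diets in that group. Marker covariates gave 0 in males at 12 h, 0 in females at 24 h, 2 in males at 96 h, 2 in both sexes at 24 h and 2 at 48 h. They gave 0 for the effect that differs by time and a correlation of 0.554 at 96 h. A fit of only the libraries compared gave 0 in males and 1 in females at 12 h, 0 in females and in both sexes at 24 h, 2 in males and 0 in both sexes at 48 h, and 97 in males and 157 in both sexes at 96 h. Its correlation at 96 h was 0.574.

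Without the 3 libraries of low similarity the counts were 3, 2, 1266 and 112 in both sexes, 25 in males at 12 h and 28 at 96 h, and 0, 181 and 5 in females at 24, 48 and 96 h. They were 12 for the effect that differs by time, 2 for 96 h minus 12 h and 8936 for time in controls. The correlations between sexes were 0.0449, 0.398 (reversed) and 0.429 at 12, 24 and 48 h. By camera's unadjusted p from the correlation set at 0.01 or estimated (fit of n = 61 libraries), lists that reversed in direction were, at 24 h, mitochondrial fatty acid and ketone oxidation (p = 0.0172), unfolded protein and amino acid response (p = 0.0098) and immune markers (p = 0.0126). For the sex difference in the effect they were NCC regulators (p = 0.97, and 0.989 with an estimated correlation) and oxidative phosphorylation (p = 0.287 and 0.806). For sex in controls they were, without and with an estimated correlation, ribosome biogenesis (p = 0.601 and 0.789), oxidative phosphorylation (p = 0.00148), heat shock (p = 0.771 and 0.909) and the sodium pump list (p = 0.994 and 0.997). Without these 3 and female furosemide 48 h replicate 2, a set tried before the similarity rule was made, the counts were 6, 9, 473 and 187 in both sexes. They were 89 and 48 in males at 12 and 96 h, 0 and 5 in females at 24 and 96 h, 8 for the sex difference at 12 h, 17 for the effect that differs by time, 9 for 96 h minus 12 h and 9156 for time in controls. The correlations were 0.0472, 0.396 (reversed) and 0.468. So the number of genes called at 48 h depends on which libraries are in, and lists were not tested without the 4. With Lars2 as a covariate the count was 0 in females at 24 h, 4 in females at 48 h, 14 in males at 96 h, and 1 and 2 in both sexes at 24 and 48 h. It was 0 for the effect that differs by time, 0 for 96 h minus 12 h and 229 for time in controls. The correlations were 0.13, 0.0438 (reversed), 0.399 and 0.648. Of the 34 genes at 96 h, 19 were among its 41. Lists that reversed at 96 h were NCC regulators (p = 0.179, and 0.614 with an estimated correlation), mitochondrial fatty acid and ketone oxidation (p = 0.000178), unfolded protein and amino acid response (p = 0.00252) and heat shock (p = 0.00337). Leaving out the 5 furosemide libraries high in Lars2 leaves 2 male and 1 female furosemide libraries at 96 h, so the female count and the sex difference rest on an arm of 1 library and say nothing on stability. The 96 h counts were then 3 in both sexes, 1 in males, 1 in females and 1 for the sex difference, and 3 for the effect that differs by time. The correlation was 0.398, the noncoding RNA gene Bc1 reversed to −0.06 (−0.058), and the same 4 lists reversed (p = 0.187, or 0.639 with an estimated correlation, 3.03e-05, 1.81e-05 and 0.00255). Without the 96 h libraries the count for time in controls was 0.

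With 1 library left out in turn, the counts in both sexes ranged over 0 to 2, 0 to 11, 0 to 6 and 18 to 90. In males they ranged over 0 to 1, 0 to 1, 0 to 0 and 1 to 5, and in females over 0 to 0, 0 to 1413, 0 to 7 and 0 to 9. Sex differences ranged over 0 to 1 at 12 h and 0 to 1069 at 24 h. The effect that differs by time ranged over 0 to 6, 96 h minus 12 h over 0 to 2, sex in controls over 416 to 590 and time in controls over 2303 to 7230. The correlations ranged over 0.0456 to 0.331, −0.22 to 0.397, 0.196 to 0.441 and 0.396 to 0.558. Depth limits genes of low level most, and between 12 and 48 h, where libraries hold fewer counts than at 96 h, a gene that was not called is not shown to be unchanged.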

Other observations

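The gene groups in the next paragraphs were fixed before the data were examined and tested with the others, and the reading of single members came after their values were seen. Clock genes pointed in opposite directions after 12 h, with members higher and lower adjusted over the list alone and 0 called over all genes. The activator gene Arntl had a log2 fold change of 0.59 (SE 0.233), against −1.42 (SE 0.561) for the output gene Dbp, −1.18 (SE 0.35) for the repressor Nr1d2 and −0.50 (SE 0.203) for Per3. After 48 h Arntl was at 0.76 (SE 0.233), Nr1d2 at −1.12 (SE 0.349) and Tef at −0.91 (SE 0.324), and after 24 h Cry1 was at 1.67 (SE 0.506). The clock score, the mean of activators minus the mean of outputs, had a difference between diets of 0.82 (0.815), 0.55 and 0.66 at 12, 24 and 48 h (SE 0.291, n = 16 libraries), with all dissections in the same morning hours per the labels. At 96 h Bhlhe40, a clock-linked repressor, was at 1.18 (SE 0.282, adjusted p = 0.0741 over all genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

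Among regulators of entry into the cycle at 96 h, Rbl1, a pocket protein that E2F factors induce, had 1.24 (SE 0.336) and Cdkn2c, a CDK inhibitor seen in cycling cells, 1.37 (SE 0.447), while the CDK inhibitor Cdkn1a had −0.82 (SE 0.23). These 3 passed adjusted over the list alone, 0 over all genes, and the G1 list was called by camera (adjusted p = 0.0121, and adjusted p = 0.401 with an estimated correlation). Irs1, the insulin receptor substrate, had −0.89 (SE 0.219) at 12 h and passed adjusted over the list alone. Genes of mitochondrial fatty acid and ketone oxidation had a median of 0.38 at 48 h (adjusted p = 0.21 with an estimated correlation), with the ketone body enzymes Bdh1 at 0.95 (SE 0.22) and Oxct1 at 0.72 (SE 0.249), the 2 that passed adjusted over the list alone. Of the calcium genes, S100g (−1.19, SE 0.49) and Trpv5 (−1.43, SE 0.608) did not pass at 96 h in either way. Klk1 (0.91, SE 0.339) and Atp2b1 (0.49, SE 0.181) passed adjusted over the list alone at 48 h.

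Further genes were called once the 3 libraries of low similarity were left out, a comparison chosen after seeing the data, and none of the following was called with all libraries. At 48 h Igfbp3, which binds insulin-like growth factors, had 2.43 (SE 0.502), Nrtn, the growth factor neurturin, 2.20 (SE 0.39), Acot7, an acyl-CoA thioesterase, 2.05 (SE 0.343), and Tubb2a, a beta-tubulin, 1.63 (SE 0.242). With all libraries these were 1.64, 0.92, 1.02 and 1.44. At 96 h Rgcc, a regulator of the cell cycle, had −2.23 (SE 0.439), Cables1, which links CDKs to kinases, −2.11 (SE 0.476), Txnip, an inhibitor of thioredoxin and of glucose uptake, −1.67 (SE 0.365), and the nuclear receptor gene Rorb 1.53 (SE 0.339). With all libraries these were −2.19, −2.09, −1.63 and 1.55. None of the 3 libraries is of 96 h, so these folds could hardly move, while the p-values, which use the spread shared by all groups, did. Of the 1266 genes called at 48 h without the 3 libraries, 662 were among the 891 that voom called with all libraries, with the same sign in 662. Both fits rest on largely the same libraries, so neither the overlap nor the sign is independent support.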
